A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

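RNA was measured by sequencing in 2 haploid MATa strains of budding yeast in the S288c background. Both carried Cre-EBD78, a Cre recombinase fused to an estradiol-binding domain, so that beta-estradiol switches it on. In the CEN4* strain lox sites flanked the centromere of chromosome IV, and cells of this strain are called cen4- once the recombinase has cut the centromere out. In the CEN4 control strain the centromere had no lox sites. Per the labels' protocols, cells grew at 30 °C in YPD, a rich glucose medium, received 1 µM beta-estradiol and came from 3 independent experiments. Total RNA was cleaned of DNA with DNase, and a sequencing company prepared the libraries. Strain and time gave 10 groups of 3 libraries, at 0, 30, 60, 120 and 180 min after beta-estradiol.

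The deposited table held 1 signal value per gene and library, a read count divided by the library's DESeq2 size factor, per the labels. STAR 2.6.1 and DESeq2 were named as tools and R64 (sacCer3) as genome build, per the submitters' processing notes. The read counter, its strand setting and the annotation release were not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Each value in all 30 libraries was a whole multiple of the library's smallest value within 1e-06 of a read (100% of values). Multiplying back gave library totals of 8218002 to 14956813 reads. The table had 7127 genes, of which 350 were at 0 in every library, and 6047 matched the R64 gene annotation by identifier, all on the chromosome that the table gave. Of the 1080 others, 648 were described as dubious reading frames. Coordinates are those of R64.

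Before averaging, the 30 pairs of replicate libraries were compared by a chi-square test of their reads over genes with at least 40 reads. Chi-square per degree of freedom was 1.48 to 7.75, so no pair differed by as little as counting noise. Intervals and detection limits cover counting error only, since reads without molecular identifiers are not independent molecules. Between 0.001% and 0.006% of the reads of a library fell on ribosomal RNA.

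Tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with the trend and robust options and a mean for each of the 10 groups (20 residual degrees of freedom). The fit held the 5948 genes with a mean of at least 10 normalised counts: 768 on chromosome IV, 5177 on the other 15 nuclear chromosomes and 3 on the mitochondrial genome. The pseudocount of 1 understates changes of weakly expressed genes. A gene was called at an adjusted p (Benjamini-Hochberg, within a comparison) below 0.05. The centromere-excision effect at a time was the change since 0 min in the cen4- strain minus the change since 0 min in CEN4. This interaction removes an effect of beta-estradiol that the strains share, and a difference at 0 min that stays constant. The strain difference at 0 min, the changes with time within each strain, and the direct difference of the strains at each time were also fitted. The 4 excision effects share the 0 min libraries, so their calls are not independent.

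Groups of genes were tested with limma's camera, which compares a group with all other tested genes, at a preset inter-gene correlation of 0.01, and again with an estimated correlation, which is stricter for genes that vary together. The family was 26 gene lists at 4 times, 104 tests. A further planned check was limma's fry, which asks whether a list moved at all, without other genes as reference. The lists included GAL genes, chromosome IV transcription factors, strain markers, condensin subunits, alpha-cell markers, a-cell and pheromone genes, meiosis and sporulation, environmental stress response, heat-shock factor targets, DNA damage response, pleiotropic drug resistance, ergosterol synthesis, G1/S genes, core histones, the G2/M CLB2 cluster, spindle checkpoint and kinetochore, ribosomal proteins, ribosome biogenesis, proteasome, glucose-repressed and respiratory genes, phosphate regulon, amino acid synthesis under Gcn4, methionine and sulfur, iron regulon, and the subtelomeric PAU and COS families. The members were chosen from textbook knowledge, not from these samples. The chromosome IV shift was the median log2 effect of its tested genes minus that of the other nuclear genes. It was also computed for each library against the 0 min mean of its strain and compared between strains by exact permutation tests (two-sided, 3 against 3, smallest possible p 0.1) and by a permutation within time points over the 24 libraries from 30 to 180 min (100000 resamples), for each of the 16 chromosomes.

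Named genes followed a rule. It took the 10 largest rises and 10 largest falls at 180 min among called genes whose 3 cen4- values all lay on one side of the 3 CEN4 values, 5 and 5 at 120 min, and 3 and 3 at 30 and at 60 min. It took 5 and 5 for the strains at 0 min and for each strain at 180 min against 0 min. It took up to 4 called members of each list with the largest change at 180 min, or the most abundant member where none was called. It also took all measured GAL, strain-marker, condensin and alpha-cell genes, and the 5 tested genes nearest to the chromosome IV centromere on each arm. Members of families with near-identical copies and overlapping genes are marked as uncertain. Groups, tests, lists, this rule and the alternatives were fixed before the data were examined, except for 3 alternatives added later: the trend on gene length removed, only genes with an annotated position, and the position classes with an estimated correlation. The comparison of list members on and off chromosome IV, the 100-kb windows and the tests marked so in the closing sections were also not fixed in advance.

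The alternatives were pseudocounts of 0.5 and 8, no filter and a mean of at least 50, scaling of each library to the same total or over genes outside chromosome IV, limma's array weights, only the groups compared in the fit, the direct difference at a time in place of the interaction, a block by the number in the sample titles, each library left out in turn, and count models on the recovered reads (edgeR 4.0.16 quasi-likelihood with TMM, DESeq2 1.42.0). Tables and figures used Python 3.11.15. The fit was tested on simulated reads for the excision effect at 180 min over 5948 genes, with real means and depths. It recovered 47.8% of 67 genes changed 1.2-fold, 85.1% of 67 changed 1.5-fold and 97.0% of 66 changed 2-fold, with 6 unchanged genes called. Far fewer genes changed there than were called in the real data, and each gene was drawn independently. The simulations below share this independence, so none of them covers genes that vary together. A simulated chromosome IV shift of 0.10 was estimated as 0.104 at 180 min, and a simulation without one as -4e-04.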

Results

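Transcripts were measured in 30 libraries, 3 for each of 10 groups, from a yeast strain whose chromosome IV centromere can be cut out by an estradiol-activated recombinase (CEN4* before and cen4- after excision) and from a control strain with the recombinase but an intact centromere (CEN4). The control received beta-estradiol too, so that the comparison of both time courses removes effects of time and beta-estradiol that the strains share. Any other difference between the strains that changes with time stays in what is called the excision effect. How many cells had lost the centromere was not measured here. Libraries held 8218002 to 14956813 reads. The 3 replicates of a group were collected in 3 independent experiments, and limma's p-values measure the spread between them. The median standard error of an excision effect was 0.08 on the log2 scale, which is used for all changes given here.

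Genes changed by mutation or used as markers in the strains came first. URA3 and MET17, which are deleted in both strains, had 0 reads in all 30 libraries; at the lowest depth, 3 reads would be 3.65e-05% of a library. LEU2, the marker carried with the recombinase, was at 3680 ± 152 (SD, n = 3) normalised counts in CEN4 and at 2049 ± 52.1 (SD, n = 3) in CEN4* cells at 0 min. HIS3, partly deleted in both, stood at 744 ± 32.5 and 724 ± 10.7 (SD, n = 3). LEU2 was lower in CEN4* cells by limma (log2 difference -0.84, adjusted p = 2.1e-26). The excision effect at 180 min was below 0 for both genes (LEU2 -0.37, limma adjusted p = 1.4e-07, and HIS3 -0.50, limma adjusted p = 4.09e-07). LEU2 did not fall in the excised strain: it rose to 2629 by 180 min, but to 6096 in CEN4 cells. HIS3 went to 552 in the excised strain and to 801 in CEN4 cells. The list of these 2 strain markers was lower relative to CEN4 at 180 min (median -0.43, camera adjusted p = 0.0484, and adjusted p = 0.122 with an estimated correlation). That call was also lost with the gene length trend removed (adjusted p = 0.0716), with a mean of at least 50 normalised counts (adjusted p = 0.0552) and without some single libraries.

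Before beta-estradiol the strains already differed in stress and iron genes. In CEN4* cells 24 of 30 environmental stress genes were higher and 2 lower, with a median log2 difference of 0.52, and 11 of 20 genes of the iron regulon were higher (median 0.24). Of 137 ribosomal protein genes, 105 were lower (median -0.16), as were 10 of 20 a-cell and pheromone genes (median -0.16) and 11 of 15 genes of the phosphate regulon (median -0.27). The single genes with the largest differences were the unnamed reading frame YLR307C-A (3.99), PAU15 (2.92), COS12 (2.53), SHC1, an activator of chitin synthesis in sporulation (2.33), and PDC6, a minor pyruvate decarboxylase (2.26). ENA5, a sodium pump (-1.67), SUP53, the leucine tRNA gene beside LEU2 (-1.38), the subtelomeric helicase copy YML133C (-1.06), TIM9, beside URA3 (-0.93), and YFL064C (-0.92) were lower. PAU15, COS12, ENA5 and YML133C have near-identical copies, YFL064C overlaps YFL065C, and TIM9 had only 17.9 ± 5.92 normalised counts in CEN4 cells (SD, n = 3), so these are uncertain. By limma, 945 of 5948 genes differed at 0 min, 525 higher and 420 lower in CEN4*, 47 of them at least 2-fold. With each library scaled to the same total, 948 were higher and 215 lower, because the median of all genes moved by 0.06. The 5 lists passed camera with an estimated correlation, adjusted over the 26 lists in 9 comparisons (stress, adjusted p = 0.0138; iron, 0.00837; ribosomal proteins, 0.0415; pheromone genes, 0.00903; phosphate, 0.0238).

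With time after beta-estradiol, stress and respiratory genes rose and ribosomal protein genes fell in both strains. From 0 to 180 min, 29 of 30 environmental stress genes rose in each strain, with a median log2 change of 2.10 in cen4- and 1.54 in CEN4 cells, and 22 and 24 of 26 glucose-repressed and respiratory genes rose (0.77 and 0.68). Ribosomal protein genes fell, 137 of 137 in cen4- (median -1.27) and 132 of 137 in CEN4 (median -0.64), and so did 20 of 24 ergosterol synthesis genes in each strain (-0.48 and -0.38). In cen4- cells the largest rises were those of GRE1, a desiccation hydrophilin (3.05), EGO4 (3.05), the glycogen phosphorylase GPH1 (2.91), the small heat-shock protein gene HSP26 (2.91) and YNL194C (2.85), and the largest falls those of the phosphate transporter PHO89 (-3.38), the glucose transporter HXT2 (-2.95), TIR1 (-2.62), ATO3 (-2.46) and DAN1 (-2.30). In CEN4 cells PDC6 (5.08), GRE1 (4.85), SIP18 (4.14), PRM6 (3.72) and SPS100 (3.66) rose most, and PHO89 (-3.90), DAN1 (-3.75), TIR1 (-3.56), PRM7 (-3.16) and BSC1 (-3.15) fell most. These list medians passed camera with an estimated correlation at adjusted p of 0.00837 to 0.0472, except that of the stress genes in cen4- cells (adjusted p = 0.0508 with an estimated correlation). By limma, 3698, 3358, 4282 and 4475 genes changed in cen4- cells at 30, 60, 120 and 180 min, and 3786, 3399, 4197 and 4237 in CEN4 cells, with 49.9% to 52.7% of them higher. Scaling to the same total moved the median of all genes by 0.12 to 0.31 in these comparisons, and 70.5% to 79.9% of the called genes were then higher.

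The excision effect covered few genes within an hour and many after it. Relative to CEN4, 110 genes had changed in cen4- cells at 30 min (50 higher and 60 lower), 173 at 60 min (53 and 120), 1550 at 120 min (707 and 843) and 2516 at 180 min (1180 and 1336), by limma over 5948 genes. None, 13, 44 and 95 of them changed at least 2-fold. Scaling to the same total moved the median of all genes by 0.10 at 180 min and 0.08 at 120 min. It gave 60 higher and 43 lower genes at 30 min, 1381 and 501 at 120 min, and 1856 and 788 at 180 min. The values below keep the deposited scaling, in which the median gene lay at -0.01 at 180 min, so that they are changes relative to the median gene. Unless a change with time is named, a rise or fall below is an excision effect. A gene said to fall may thus have risen in cen4- cells, but by less than in CEN4.

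**Figure D1:**
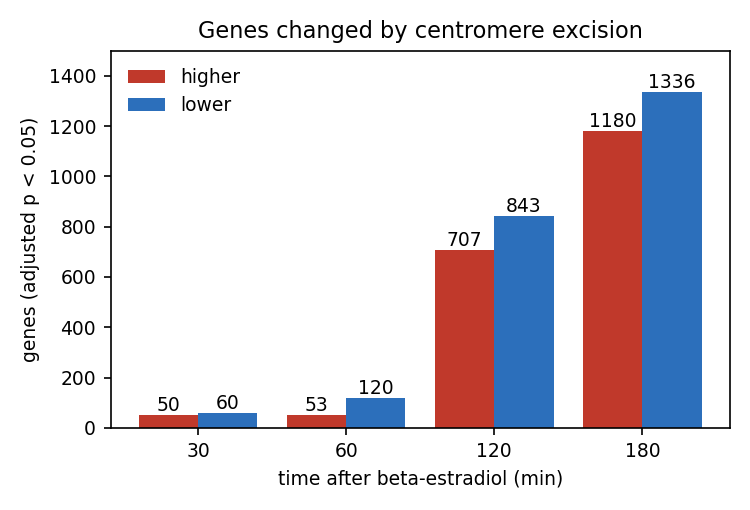
Number of genes called by limma (adjusted p below 0.05) for the excision effect, on the y axis, at each time after beta-estradiol in min, on the x axis, with higher and lower genes as separate bars. The bars grow from 50 and 60 genes at 30 min to 1180 and 1336 at 180 min.

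At 30 min chaperone, sulfur and G2/M genes were higher by small amounts, and histone genes lower. The methionine and sulfur list rose, with 4 of 19 genes higher (7 adjusted over the list alone) and a median of 0.13, as did the heat-shock factor targets (6 of 20 higher, 11 adjusted over the list alone; median 0.16) and the G2/M cluster (6 of 21 higher, 12 adjusted over the list alone, and 1 lower there; median 0.16). Of 8 core histone genes 4 were lower (6 adjusted over the list alone; median -0.18; camera adjusted p = 5.89e-08; adjusted p = 0.0717 with an estimated correlation). Ribosomal protein genes (4 of 137 lower, 7 adjusted over the list alone; median -0.09) and G1/S genes (1 of 25 lower, 5 adjusted over the list alone; median -0.09) had camera adjusted p of 1.62e-18 and 7.19e-04, and adjusted p = 0.173 and 0.16 with an estimated correlation. STR3, a cystathionine lyase (0.93), the glycogen debranching enzyme GDB1 (0.53) and AQY3 (0.51) rose most, and PDC6 (-0.85), the proteinase inhibitor PAI3 (-0.80) and HSP12 (-0.78) fell most. By limma the adjusted p of these 6 genes were 5.52e-05 to 0.0287, and camera with an estimated correlation gave an adjusted p of 1.77e-04 for sulfur genes and 0.0114 for heat-shock factor targets and for the G2/M cluster, over 104 tests. PDC6, PAI3 and HSP12 were higher in CEN4* than in CEN4 cells at 0 min, by 2.26, 1.30 and 1.74. The count at this time depended on single libraries: it was 71, 73 and 68 without CEN4 t0 replicate 1, CEN4* t0 replicate 2 and cen4- t30 replicate 1, and 196 with array weights.

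At 60 min methionine and sulfur genes were higher again (4 of 19, 6 adjusted over the list alone; median 0.15; camera adjusted p = 1.77e-04 with an estimated correlation). Of 30 environmental stress genes 9 were lower and 1 higher, with 15 and 1 adjusted over the list alone and a median of -0.22 (camera adjusted p = 6.86e-19; adjusted p = 0.0711 with an estimated correlation), a list that stood 0.52 higher in CEN4* cells at 0 min. Ribosomal protein genes (14 of 137 lower, 41 adjusted over the list alone; median -0.10), core histone genes (3 of 8 lower, 4 adjusted over the list alone; median -0.12) and G1/S genes (1 of 25 lower, 4 adjusted over the list alone; median -0.12) had camera adjusted p of 1.95e-13, 1.98e-04 and 1.48e-04, and adjusted p = 0.268, 0.212 and 0.117 with an estimated correlation. DAN1, a cell wall mannoprotein (1.49), the dubious frame YLR294C (0.94) and THI2, an activator of thiamine genes (0.92), rose most, and PDC6 (-1.77), the aldehyde dehydrogenase ALD3 (-1.41) and PHM7 (-1.37) fell most; the latter 3 were higher in CEN4* cells at 0 min, by 2.26, 1.36 and 1.78. All 6 passed limma at adjusted p of 1.81e-09 to 0.00891. Array weights gave 388 genes at this time, and leaving out cen4- t60 replicate 3 gave 271.

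At 120 min ribosomal protein and pheromone genes had fallen and chaperone and sulfur genes had risen. Ribosomal protein genes were lower in 122 of 137 cases (125 adjusted over the list alone; median -0.45), and a-cell and pheromone genes in 12 of 20 (14 adjusted over the list alone; median -0.30). Heat-shock factor targets were higher in 18 of 20 cases (18 adjusted over the list alone; median 0.46), and methionine and sulfur genes in 13 of 19 (14 adjusted over the list alone; median 0.27). With an estimated correlation camera gave adjusted p of 0.00341, 0.00183, 0.0112 and 1.77e-04 for these lists. The G2/M cluster had 12 of 21 genes higher and none lower (median 0.21, camera adjusted p = 4.66e-04; adjusted p = 0.189 with an estimated correlation). Of 8 core histone genes 7 were lower (8 adjusted over the list alone; median -0.36; camera adjusted p = 1.09e-08; adjusted p = 0.0711 with an estimated correlation). The hexose transporter HXT10 (1.76), SOE1, a glutamate tRNA (1.6), YPL205C (1.43), the dubious frame YML099W-A (1.30) and YDR215C (1.29) rose most. PDC6 (-2.53), GRE1 (-2.02), SIP18, another hydrophilin (-1.81), SPS100 (-1.66) and ANS1 (-1.6) fell most; these 5 were 0.76 to 2.26 higher in CEN4* cells at 0 min. SPS100 overlaps the transcript SUT169 and is uncertain. The adjusted p of these 10 genes by limma were 4.61e-12 to 0.0396.

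By 180 min GCV2 (-1.94) and GCV3 (-1.73), subunits of mitochondrial glycine decarboxylase, fell: GCV2 (YMR189W, chromosome XIII, 637500 to 640604) went from 923 ± 58.5 to 3887 ± 150 normalised counts in CEN4 cells and from 1099 ± 29.8 to 1206 ± 43.4 in the excised strain (SD, n = 3). The pheromone-regulated genes PRM6 (-2.94), FIG1 (-2.04) and AGA1, the anchor of a-agglutinin (-1.61), fell too, with AGA1 (YNR044W, chromosome XIV, 703699 to 705876) at 3691 ± 127 in CEN4 and 974 ± 46.5 in cen4- cells at 180 min (SD, n = 3). GDB1 (YPR184W, chromosome XVI, 902044 to 906654) rose by 1.74, from 342 ± 15.8 to 2050 ± 12.3 in the excised strain against 267 ± 20.7 to 476 ± 16.6 in CEN4 (SD, n = 3), and the heme oxygenase HMX1 rose by 1.53 and the putative chaperone JID1 by 1.48. By limma the adjusted p were 6.44e-34 for GCV2, 3.54e-35 for GCV3, 2.69e-23 for AGA1, 4.57e-04 for PRM6 and 9.7e-07 for FIG1. They were 2.52e-25 for GDB1, 8.75e-11 for HMX1 and 1.44e-10 for JID1.

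The other rises among the 10 largest, all of genes with few reads, were those of the dubious frames YIR040C (2.18) and YML099W-A (1.97), PAU3 (1.90), SPS22 (1.63), LSO1 (1.54), the sporulation kinase gene SPS1 (1.48) and the formate dehydrogenase gene FDH1 (1.47). PAU3 has near-identical copies, and FDH1 stood at 26.6 ± 4.37 normalised counts in cen4- and 9.81 ± 6.63 in CEN4 cells (SD, n = 3). The limma adjusted p of these 7 were 6.22e-04 to 0.00615. The other falls among the 10 largest were those of PDC6 (-2.41), YDR340W (-1.93), GRE1 (-1.80), the dubious frame YLR279W (-1.62) and the short frame RDT1 (-1.62), at limma adjusted p of 8.11e-12 to 0.0088. PDC6 and GRE1 were 2.26 and 1.32 higher in CEN4* cells at 0 min. At 180 min itself PDC6 differed between the strains by -0.16 (limma adjusted p = 0.387), while the other 9 genes with the largest falls were lower and all 10 with the largest rises were higher in cen4- than in CEN4 cells of that time.

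Protein-folding and sulfur genes led the groups that rose at 180 min. All 20 heat-shock factor targets were higher, with a median of 0.65, among them AHA1, a co-chaperone of Hsp90 (1.29), CUR1 (1.15), the Hsp70 gene SSA2 (1.01) and STI1 (0.94). Of 19 methionine and sulfur genes 16 were higher (median 0.59), with the sulfite reductase gene MET5 at 1.27, MET14 at 1.21, STR3 at 1.2 and MET3 at 1.15. Camera gave adjusted p of 4.72e-19 and 1.53e-11, and with an estimated correlation 0.0104 and 3.94e-05, over 104 tests. The iron regulon followed with 12 of 20 genes higher and 2 lower (median 0.35; camera adjusted p = 4.26e-04; adjusted p = 0.0711 with an estimated correlation): HMX1, the cell wall siderophore genes FIT3 (1.38) and FIT1 (0.88) and the siderophore transporter gene SIT1 (0.88) rose, while FET3 and FTR1, which form the high-affinity iron uptake complex, fell (-0.51 and -0.36; both named after their values were seen). Of 30 environmental stress genes 16 were higher (19 adjusted over the list alone) and 6 lower (median 0.33; camera adjusted p = 1.05e-04; adjusted p = 0.467 with an estimated correlation). Its members GDB1, the phosphogluconolactonase SOL4 (1.30) and the glucokinase GLK1 (0.94, overlapping YCL042W) rose, while ALD3 fell (-0.81). Of 15 pleiotropic drug resistance genes 6 were higher (median 0.23; camera adjusted p = 0.00492; adjusted p = 0.0717 with an estimated correlation), with the exporter genes TPO1 (1.01), SNQ2 (0.64) and PDR15 (0.51) and YGR035C (0.87).

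Relative to CEN4, mating, ribosomal protein and S-phase genes led the groups that were lower at 180 min. As lists, core histone, G1/S and kinetochore genes did not fall since 0 min in cen4- cells (medians 0.18, 0.13 and 0.04). They rose by more in CEN4 cells (medians 0.68, 0.29 and 0.32). Of 20 a-cell and pheromone genes 18 were lower (median -0.63), including PRM6, FIG1, AGA1 and the a-factor gene MFA1 (-1.52); the list's median change since 0 min was -0.34 in cen4- and 0.26 in CEN4 cells. Of 137 ribosomal protein genes 124 were lower (126 adjusted over the list alone) and none higher (median -0.65), with RPL43B (-1.13), RPS31 (-1.13), RPL9A (-1.06) and RPS22B (-0.95, overlapping SNR44) farthest down; RPL43B, RPL9A and RPS22B have near-identical paralogs. Camera gave adjusted p of 1.09e-12 and 5.32e-72, and with an estimated correlation 1.77e-04 and 0.00661. All 8 core histone genes were lower (median -0.51; camera adjusted p = 4.9e-08; adjusted p = 0.0714 with an estimated correlation), HHF1 at -0.80, HHT1 at -0.77, HTA2 at -0.56 and HTA1 at -0.54, each one of a pair of near-identical copies. Of 25 G1/S genes 17 were lower (19 adjusted over the list alone) and 1 higher (median -0.27; camera adjusted p = 2.5e-04; adjusted p = 0.129 with an estimated correlation), among them the G1 cyclin gene CLN2 (-0.52), the polymerase gene POL12 (-0.47), TOS4 (-0.46) and the S-phase cyclin gene CLB6 (-0.44). Of 22 spindle checkpoint and kinetochore genes 10 were lower (median -0.18; camera adjusted p = 0.0295; adjusted p = 0.0714 with an estimated correlation), led by SPC25 (-0.54), NSL1 (-0.52), SPC24 (-0.47) and DUO1 (-0.46).

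**Figure D2:**
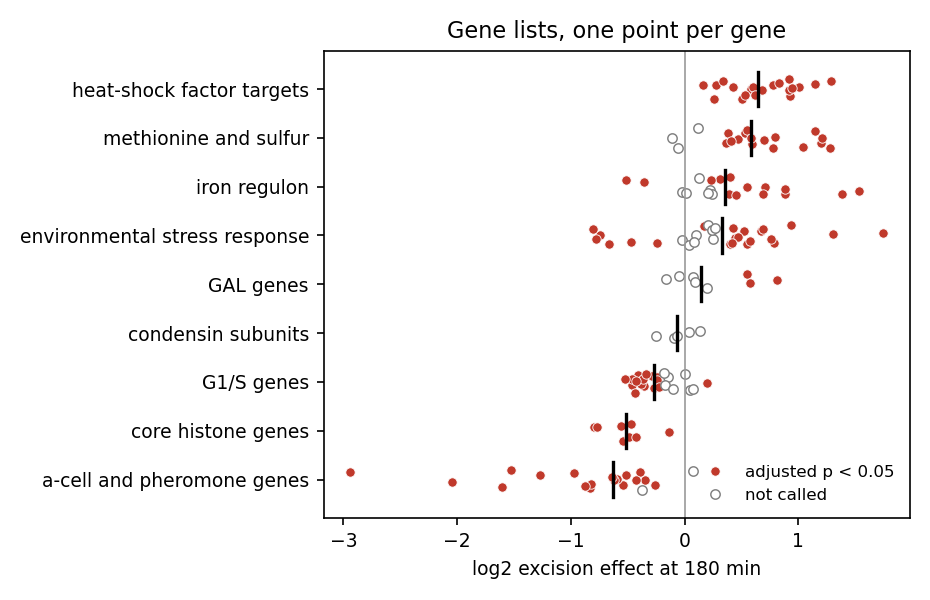
Log2 excision effect at 180 min (x axis) of each tested gene in 9 of the gene lists (y axis), 1 point per gene; filled points were called by limma and black bars are list medians. The heat-shock factor targets lie around 0.65 and the a-cell and pheromone genes around -0.63, while the 5 condensin genes show no call.

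Other lists held genes that moved both ways, and none of them passed camera at 180 min. They were G2/M genes (6 of 21 higher and 4 lower; DBF2 0.47, IQG1 0.35, KIN3 0.30, CLB1 -0.27), DNA damage genes (4 of 19 higher and 1 lower; RNR3 0.45, RAD16 0.44, RAD2 0.42, RNR1 -0.41), and meiosis and sporulation genes (4 of 21 higher and 2 lower; SPS1 1.48, SPS100 -1.45, SPS4 -0.76, DIT1 0.61). Of 25 genes of amino acid synthesis 6 were higher and 8 lower, SER3 at 1.33 (overlapping SRG1), LYS20 at 1.01, HIS4 at -0.72 and SNZ1 at -0.49. Of 15 phosphate genes 6 were higher and 3 lower (PHO89 0.52, PHM8 0.50, PHO84 -0.32, PHO8 0.31). Of 26 glucose-repressed and respiratory genes 6 were higher and 6 lower (CAT8 0.81, PCK1 -0.69, JEN1 0.63, CIT2 0.49). Of 24 ergosterol genes 2 were higher and 9 lower (ERG9 0.39, ERG2 -0.35, HMG1 0.29, ERG26 -0.23), and of 40 ribosome biogenesis genes 4 were higher and 4 lower (NIP7 -0.34, FAL1 0.30, UTP4 0.29, NOP56 -0.20). Of 23 PAU and COS genes, uncertain for their shared reads, 4 were higher and 3 lower (PAU3 1.90, COS12 -1.34, COS111 0.61, COS7 -0.55). Camera's adjusted p at 180 min for these 9 lists were 0.32 to 0.918. By fry, which does not compare with other genes, ergosterol genes passed downward and PAU and COS genes upward (fry adjusted p = 0.00479 for both). Counts adjusted over the list alone differed from those over all genes only where given for the lists at 180 min and for the G2/M (7 higher), phosphate (4 lower), ribosome biogenesis (3 higher and 3 lower) and chromosome IV transcription factor lists (3 lower).

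GAL genes, condensin genes and genes of the opposite mating type showed little. GAL7 (0.81), the reductase gene GCY1 (0.57) and GAL2, the galactose permease gene (0.55), rose by 180 min by limma (adjusted p = 0.0141, 1.1e-04 and 0.0116), while GAL10 (0.20), GAL3 (0.09), GAL1 (0.07), GAL4 (-0.05) and GAL80 (-0.16) were not called. The GAL list did not pass camera (median 0.14, adjusted p = 0.384). It did pass fry, in the upward direction (fry adjusted p = 0.00942). None of the 5 condensin genes was called: SMC2 was at -0.09, SMC4 at -0.07, BRN1 at -0.25, YCG1 at 0.14 and YCS4 at 0.04 (limma adjusted p of 0.0897 to 0.736); YCG1 was called at 0.24 with each library scaled to the same total. None of the alpha-cell genes MF(ALPHA)1 (-0.25), MF(ALPHA)2 (0.19), STE3 (0.01) and SAG1 (0.18) was called at 180 min (limma adjusted p of 0.0952 to 0.978), though SAG1 was, at 0.29, with each library scaled to the same total, and neither the condensin nor the alpha-cell list passed camera (adjusted p = 0.935 and 0.722).

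Genes of chromosome IV itself moved up against the rest of the genome. At 180 min 293 of its 768 tested genes (38.2%) were higher and 91 (11.8%) lower, against 17.1% and 24% of 5177 genes on the other chromosomes. The chromosome IV shift was 0.03 at 30 min, 0.04 at 60 min, 0.13 at 120 min and 0.17 at 180 min, where it equals 1.13-fold. Of 22 transcription factor genes on this chromosome 10 were higher and 2 lower at 180 min (median 0.12), among them ADR1, an activator of glucose-repressed genes (0.88), PHO2 (0.68), YAP6 (0.54) and RPN4, the activator of proteasome genes (0.53). The list passed camera at adjusted p = 0.026 (adjusted p = 0.224 with an estimated correlation). With the gene length trend removed it did not, and its median relative to other genes fell to 0.05 from 0.13 (camera adjusted p = 0.0764). All 22 genes lie on chromosome IV, whose shift by itself raises the list against other genes. The list was not tested against the rest of the chromosome, so its pass does not single out transcription factors. For the whole chromosome camera gave p = 0.0516, 4.94e-04, 1.16e-07 and 1.07e-07 at the 4 times, and 0.139, 0.0121, 4.42e-04 and 4.3e-04 with an estimated correlation. Over 16 chromosomes the adjusted p were 0.826, 0.00791, 1.86e-06 and 1.71e-06, and with an estimated correlation 0.556, 0.194, 0.00707 and 0.00688. CEN4* cells already showed a shift of 0.05 at 0 min (camera p = 0.00636; p = 0.0431 with an estimated correlation; adjusted p = 0.102 over 16 chromosomes).

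Library by library, the shift since 0 min was -0.014 ± 0.0079 in CEN4 and 0.212 ± 0.0141 in cen4- cells at 180 min (SD, n = 3). At 120 min it was -0.0086 ± 0.0176 and 0.14 ± 0.012, at 60 min -4e-04 ± 0.0065 and 0.0411 ± 0.0335, and at 30 min 0.0044 ± 0.0028 and 0.0152 ± 0.0069 (SD, n = 3). All 3 cen4- libraries lay above all CEN4 libraries at 30, 120 and 180 min (exact permutation p = 0.1, the smallest that 3 against 3 allow), and 2 did at 60 min (exact permutation p = 0.2), where cen4- t60 replicate 3 was at 0.0026. Over all 4 times the strains differed by 0.107 (permutation within times, p = 4e-05, adjusted p = 3.2e-04 over 16 chromosomes). This permutation treats libraries of different times as independent, although the replicates came from 3 independent experiments. If the experiments are the units, 3 against 3 allow no p below 0.1. Both permutation tests held the 0 min mean of each strain fixed, so their p leave out the spread at 0 min. An error in those means is shared by all later libraries of a strain and counts here as a difference. The other chromosomes differed by -0.0318 (chromosome II) to 0.0013, and 10 of these 15 had an adjusted p below 0.05, all with values below 0. Chromosome IV was among the genes that each was compared with, so its rise lowers their values. With so many chromosomes passing, the p over all times is weak evidence by itself.

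**Figure D3:**
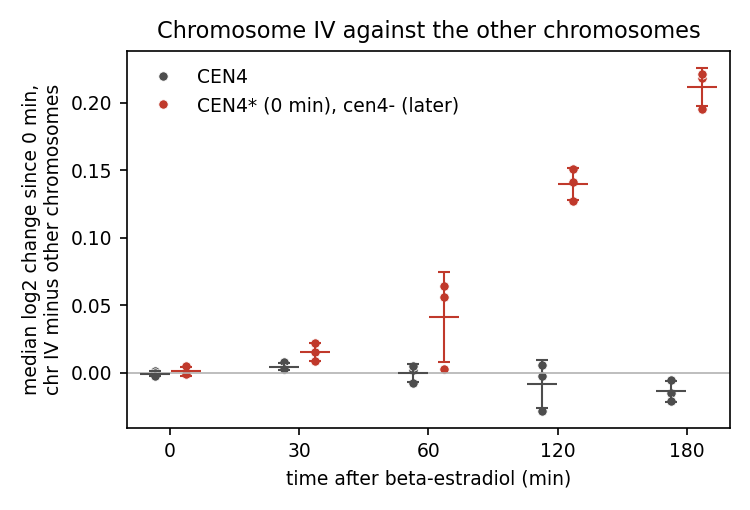
Median log2 change since 0 min of chromosome IV genes minus that of genes on the other chromosomes (y axis) at each time after beta-estradiol in min (x axis), 1 point per library, with mean and SD (n = 3). The cen4- libraries reach 0.196 to 0.221 at 180 min, and the CEN4 libraries lie between -0.0214 and -0.0057 there.

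The shift extended along the whole chromosome. All 16 windows of 100 kb lay above 0 at 180 min, between 0.08 and 0.30, and the left and right arms shifted by 0.17 each (camera adjusted p = 9.59e-07 and 3.66e-06; 0.00402 for both with an estimated correlation). Genes up to 50 kb from the centromere shifted by 0.12 (51 genes), those at 50 to 200 kb by 0.15 (149 genes) and those beyond 200 kb by 0.19 (527 genes), with camera adjusted p of 0.0474, 1.48e-04 and 2.96e-07 (0.0455, 0.0213 and 0.00402 with an estimated correlation); the classes were not tested against each other. The 16 genes within 30 kb of an end, at 0.23, did not pass (adjusted p = 0.136). Of the 10 genes nearest to the excised centromere (chromosome IV, 449711 to 449821), RMD1, 447984 to 449276, rose (0.47, limma adjusted p = 5.32e-05), and the cohesin gene MCD1 (-0.24, adjusted p = 0.00581) and the trehalase gene NTH1 (-0.20, adjusted p = 0.0131) fell. NHP10 (0.04), ATP16 (0.08), MED2 (0.15), YRB1 (0.01), RCR2 (0.05), YDR003W-A (0.10) and RAD57 (0.14) were not called. With each library scaled to the same total, MCD1 (-0.14) and NTH1 (-0.10) were not called, and ATP16 (0.19), MED2 (0.25) and RAD57 (0.25) were called. The last window, at the right end, held 7 genes. All 16 windows also lay above 0 in the difference of CEN4* from CEN4 cells at 0 min, between 0.02 and 0.08.

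**Figure D4:**
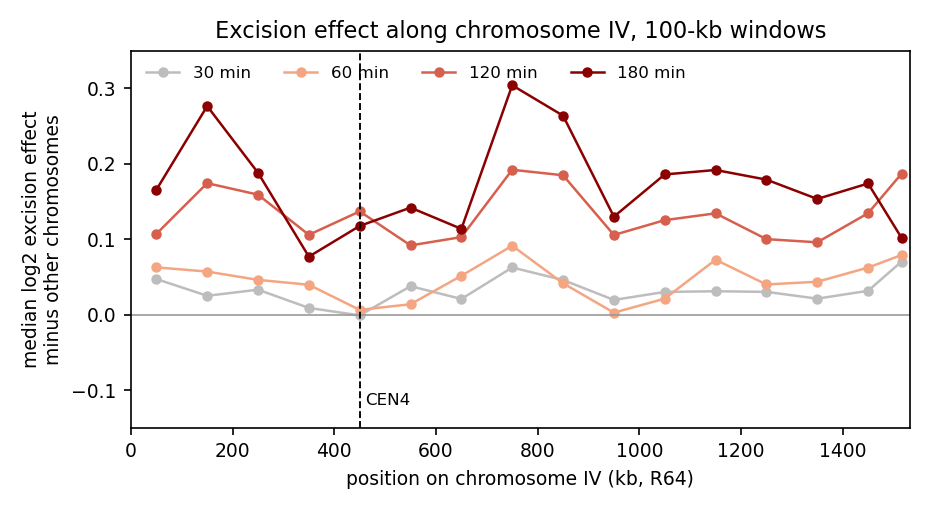
Chromosome IV shift (y axis, median log2 excision effect minus that of other chromosomes) in 100-kb windows along the chromosome (x axis, kb in R64), 1 line per time, with the centromere as a dashed line. All windows lie above 0 at 180 min, from 0.08 to 0.30.

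Members of the same complex differed by chromosome. The proteasome list did not pass camera (6 of 33 genes higher and 9 lower, median -0.05, adjusted p = 0.722), but all 5 of its members on chromosome IV rose, RPT2 by 0.83, RPN6 by 0.76, RPT3 by 0.75, RPN9 by 0.73 and RPN5 by 0.70, and the only other member called higher was RPN1 (0.29); RPN5 and RPN1 were named after their values were seen. RPT2 (YDL007W, chromosome IV, 438047 to 439360) went from 4182 ± 87.4 to 8949 ± 187 normalised counts in the excised strain and from 3477 ± 70.3 to 4184 ± 9.14 in CEN4 cells (SD, n = 3). The 28 members on other chromosomes had a median of -0.08. The 19 ribosomal protein genes on chromosome IV had a median of -0.17, and the 118 others one of -0.66. The comparison of members by chromosome was not planned before the data were examined, so its p-values describe a pattern found in these same data. Across genes, which are not independent replicates, members on and off the chromosome differed at 180 min. For the proteasome the exact permutation p was 4.2e-06 (adjusted p = 1.47e-05). For ribosomal proteins the permutation p was 1e-05, the smallest that the resamples can give (adjusted p = 1.56e-05). In the change of CEN4 cells from 0 to 180 min the differences between such members gave p of 0.24 and 0.76 by the same permutation tests. The proteasome members on chromosome IV were also higher in CEN4* cells at 0 min, with a median of 0.22 against -0.04 for the others (exact permutation adjusted p = 1.56e-05), and the ribosomal protein genes on it were at -0.07 there, against -0.17 for the others (permutation adjusted p = 7.64e-05). In the excision effect at 30 min the ribosomal protein genes on and off the chromosome gave a permutation p of 0.68. The proteasome genes differed at that time, with medians of 0.13 on and -0.0043 off the chromosome (exact permutation p = 2.5e-05, adjusted p = 3.5e-05).

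**Figure D5:**
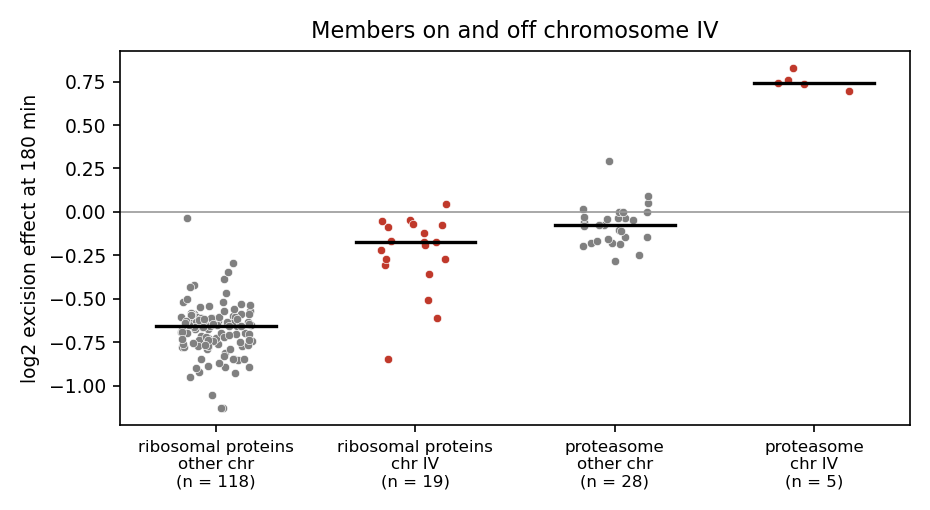
Log2 excision effect at 180 min (y axis) of ribosomal protein and proteasome genes on chromosome IV and on other chromosomes (x axis), 1 point per gene with the median as a bar. The 5 proteasome genes of chromosome IV lie between 0.70 and 0.83, above all 28 others, of which the highest is at 0.29.

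Over the 104 list tests, 43 passed with the preset correlation (21 higher and 22 lower) and 13 with an estimated one (8 higher and 5 lower). The 13 included the lists of methionine and sulfur at all 4 times, heat-shock factor targets at 30, 120 and 180 min, pheromone genes and ribosomal proteins at 120 and 180 min, and G2/M genes at 30 min. Scaling to the same total left each list at 180 min on its side of the threshold, and turned the medians of condensin (-0.07 to 0.03), ergosterol (-0.07 to 0.04), ribosome biogenesis (-0.04 to 0.06), proteasome (-0.05 to 0.06) and Gcn4 genes (-0.06 to 0.05), none of which had passed. ERG26 (-0.13) and NOP56 (-0.09) were not called under it.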

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

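The tests of gene length, of a common factor, of more copies of the chromosome, of the difference between the strains at 0 min and of other splits of the libraries were chosen after the result was seen.

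Several effects differed between the strains by the interaction test at 180 min. The chromosome IV shift differed by 0.1717. List medians differed by -0.6306 for a-cell and pheromone genes, 0.6485 for heat-shock factor targets, -0.6488 for ribosomal proteins and 0.5857 for methionine and sulfur genes. Single genes that changed with time in opposite directions in the strains, with each change and the interaction called by limma, numbered 7 at 60 min, 102 at 120 min and 225 at 180 min. Examples, chosen after their values were seen, were AAD4 (0.38 in cen4- and -0.29 in CEN4 cells) and the uridine permease gene FUI1 (-0.30 and 0.13) at 60 min. At 120 min they were HOP2 (-0.43 and 0.81) and HXT13 (0.56 and -0.46), and at 180 min GCV3 (-0.26 and 1.48), AGA1 (-0.47 and 1.14) and SHM2, a serine hydroxymethyltransferase (-0.55 and 0.83). Single libraries were not tested for lying apart within groups of 3; cen4- t60 replicate 3 had a chromosome IV shift of 0.0026 against 0.056 and 0.0645 in the others of its group.

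Chromosome IV genes rose against other genes at 180 min. A gene length trend was argued against by a shift of 0.1765 with the trend removed, and overlapping or dubious reading frames by a shift of 0.1697 without them. A common factor for all chromosome IV genes would leave members of 1 complex alike after the shift is taken off, but proteasome genes on the chromosome stayed 0.6587 above those elsewhere (exact permutation p = 4.2e-06). More copies of the whole chromosome in part of the cells, which could follow from uneven segregation after the centromere is lost, would raise all regions. In the excision effect 16 of 16 windows lay above 0, between 0.08 and 0.30. All 16 also lay above 0 in CEN4* against CEN4 cells at 0 min (0.02 to 0.08), before beta-estradiol. The excision effect leaves that earlier difference out, and its origin was not tested. More copies stay open as an explanation, as does an effect on transcription itself, since no DNA was measured here and the proteasome genes need more than such a common factor.

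Ribosomal protein genes fell at 180 min. A gene length trend was argued against by a median of -0.5691 relative to other genes with the trend removed (camera adjusted p = 1.09e-70). Their high expression level was argued against by genes of other functions, picked as nearest in mean level to each ribosomal protein gene. The picks had a median of -0.1525 (quartiles -0.42 and 0.04) against -0.65. They came from 154 different genes, each counted as often as it was picked, and how close the match was at the highest levels was not examined. The loss of the centromere or a slower growth of the cells after it may underlie the fall. Growth was not measured, so the 2 were not told apart.

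Several of the genes with the largest falls at 180 min had started higher in CEN4* cells. A difference between the strains at 0 min was argued against as the whole cause for 9 of the 10 genes, which were lower in cen4- cells at 180 min itself. For 1 gene, PDC6, it fits: the strains differed by -0.16 at 180 min (limma adjusted p = 0.387) and by 2.26 at 0 min. PDC6 reached 489 ± 35 normalised counts in cen4- and 545 ± 31.3 in CEN4 cells (SD, n = 3).

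Other splits of the libraries showed how far grouping by chance reaches. For the strains at 0 min and for the 8 changes with time, 1 of 10 splits was as large as the real one, namely the real one itself, and 10 splits are too few for a share under 0.05. The real counts were 945 for the strains at 0 min (highest other 0) and 3358 to 4475 for the changes with time (highest other 15, for CEN4 cells at 30 min, and 0 elsewhere). For the excision effect, counts as large as the real ones came in 12 of 100 splits at 30 min (real 110, highest other 2094) and 14 at 60 min (173 and 1046). They came in 15 at 120 min (1550 and 2992) and 11 at 180 min (2516 and 3190). This count cannot decide on grouping by chance, because it includes splits that hold the real difference between the strains. At 180 min, 31 of 100 splits gave as many list calls (12, highest other 17) and 11 of 100 as large a chromosome IV shift (0.17, highest other 0.24).

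Many of those splits kept the strains whole at the later time and so held their difference there: 7, 10, 14 and 10 splits besides the real one, and all of these were as large in number of genes. Among splits that mixed the strains at the later time, 4 of 92 were as large at 30 min (highest 517), 3 of 89 at 60 min (622), none of 85 at 120 min (332) and none of 89 at 180 min (80). Splits that kept the strains whole at 0 min were not taken out of these, and they hold the strain difference at 0 min. The shares at 30 and 60 min therefore cannot be read as those of random groups. The chromosome IV shift was reached by none of 89 mixed splits (highest 0.138). List calls were reached by 22 of 89, so calls with the preset correlation alone are weak evidence.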

How the results depend on the processing

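The alternatives with the gene length trend removed and with only annotated genes were chosen after the results were seen. No named gene and no list at 180 min that had passed turned its direction in the alternatives run on them, which did not include the direct difference. Lists at other times were not compared in this way. As a direct difference at 60 min, the environmental stress list had a median of 0.29, against -0.22 for the excision effect. The balance of higher and lower genes did turn. At 180 min it went from 1180 higher and 1336 lower to 1856 and 788 with each library scaled to the same total, 1287 and 1197 with scaling over genes outside chromosome IV, and 1250 and 1095 with the length trend removed. At 120 min it went from 707 and 843 to 1381 and 501, 780 and 773, and 608 and 595. At 30 min it went from 50 and 60 to 60 and 43 with each library scaled to the same total, and to 50 and 47 with edgeR. The counts were 1203 to 1882 at 120 min and 2329 to 2746 at 180 min in the models other than the direct difference. By its p unadjusted over chromosomes, the chromosome IV shift at 60, 120 and 180 min kept its side of the threshold wherever it was run; adjusted over 16 chromosomes it lost the call at 60 min with an estimated correlation (adjusted p = 0.194). At 180 min it was 0.1575 to 0.181 with 1 library left out, 0.215 as the direct difference and 0.163 to 0.1765 otherwise. It was not run with array weights, only the groups compared, the block, edgeR or DESeq2. With 1 library left out, the counts were 1321 to 1582 and 2302 to 2406, that of the strains at 0 min 742 to 848, and 40 to 46 lists passed.

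Results at 30 and 60 min moved most, and the cause was not tested unless given. Array weights gave 196 genes at 30 min and 388 at 60 min, against 110 and 173. Leaving out 1 library gave 68 to 152 genes at 30 min and 132 to 271 at 60 min; the highest was without cen4- t60 replicate 3. The chromosome IV shift at 30 min (0.0286) missed the threshold narrowly and passed it at 0.0281 with a mean of at least 50, 0.0283 with each library scaled to the same total, 0.0283 with the length trend removed, 0.0283 with only annotated genes and 0.0687 as the direct difference. Leaving out 1 library gave 0.0236 to 0.0312, past the threshold in 4 of 12 cases. The direct difference gave 1799, 1608, 3140 and 3815 genes at the 4 times, by construction, as it keeps the strain difference at 0 min and has a smaller standard error. With an estimated correlation 13 of 104 list tests passed, against 43.

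The replicate block by title number gave 955 genes at 0 min and 139, 196, 1552 and 2516 for the excision effect. Residuals of libraries with the same number correlated at -0.101 to 0.119 in 15 pairs, and 6 of these pairs matched best with their own number, so the numbers were not taken as pairs. The block was not run for the changes with time. These numbers link only the strains at the same time. A block by independent experiment across times was not fitted, so pairing of that kind was not tested. edgeR and DESeq2 called 2495 and 2329 genes at 180 min, of which limma shared 2365 and 2317. Depth limits genes without reads: 3 reads in the smallest library are 3.65e-05% of it.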

Other observations

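The test of promoter class named in this part was chosen after the result was seen.

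Both time courses held further gene groups. From 0 to 180 min 15 of 19 DNA damage genes rose in each strain (median 0.38 in cen4- and 0.40 in CEN4), with camera adjusted p = 0.0472 with an estimated correlation for both. All 20 heat-shock factor targets rose in cen4- cells (median 1.22; adjusted p = 0.0472 with an estimated correlation), while in CEN4 cells 15 were higher and 4 lower (median 0.50; camera adjusted p = 0.00165; adjusted p = 0.317 with an estimated correlation). In CEN4 cells 16 of 22 spindle checkpoint and kinetochore genes rose (median 0.32; camera adjusted p = 0.0472 with an estimated correlation), and all 8 core histone genes were higher (median 0.68; camera adjusted p = 2.68e-06; adjusted p = 0.0977 with an estimated correlation). Of 40 ribosome biogenesis genes, 39 were lower in cen4- (median -0.62) and 40 in CEN4 cells (median -0.56), at camera adjusted p of 7.85e-12 and 5.47e-14, and at adjusted p = 0.187 and 0.149 with an estimated correlation.

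At 0 min 3 more lists were higher in CEN4* cells by camera with an estimated correlation: heat-shock factor targets (11 of 20 higher and 1 lower, median 0.13, adjusted p = 0.0472), DNA damage genes (7 of 19 higher, median 0.13, adjusted p = 0.0447) and the uncertain PAU and COS families (6 of 23 higher, median 0.20, adjusted p = 0.0162). The 10 most abundant genes took 9.06% of the reads in CEN4 and 8.97% in CEN4* cells at 0 min, and 8.06% and 7.43% at 180 min. Across 4853 genes the excision effect correlated with log2 gene length at r = 0.198 at 30 min, 0.035 at 60 min, 0.338 at 120 min and 0.206 at 180 min, and with the trend removed 1203 genes were called at 120 min, against 1550.

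A hypothesis was that genes with a TATA-like promoter element on chromosome IV shifted by more than its TATA-box genes. At 180 min the 459 TATA-like genes shifted by 0.187 against such genes on other chromosomes and the 94 TATA-box genes by 0.109, a difference of 0.0777 (permutation p = 0.024, 10000 draws over genes, which are not independent). The value fits the hypothesis but came from the same data that raised it.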
